A study of Homo sapiens with 6 samples.

How the data were processed

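RNA from 6 samples of the gastric cancer cell line AGS was converted to messenger RNA libraries with a DNBSEQ kit for eukaryotic mRNA, per the labels' protocols. The labels place 3 samples in a control group and 3 in a group overexpressing ANGPTL4. The first control is labelled as a control cell and the others as vector cells, and all 3 were treated as 1 group. Sample titles are numbered 1 lower than the sample descriptions, and the table's columns carry the numbers of the descriptions, which were used to join columns to samples. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and any filters are not given in the sources used here.

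The deposited table held 17225 genes with a gene ID, a symbol and annotation terms, and 2 units side by side. TPM (each gene's length-scaled share of a library, set to a fixed total), per the file headers, was given for all 6 libraries, and each library summed to 1000000. FPKM (fragments per length of transcript and per mapped fragments), per the file headers, was given in 6 columns, of which 5 were distinct. One FPKM column name of the overexpression group occurs 2 times with identical values in every gene, and no FPKM column carried the name of the third overexpression library. That repeated column is the 1 column of per-sample values that was not mapped to a sample. It was used only to show what entering it does to the calls. Within a library TPM was a constant multiple of FPKM, with medians from 1.76 to 1.78, so the 2 units differ by scale alone, and the TPM columns were used for all main results. No pair of TPM columns was identical.

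The table gave no read counts, so tests that need counts and alternatives based on them were not run, and the test written for normalized values was used. The absolute depth of each library is unknown, and no interval for counting error could be given. The smallest steps of TPM in genes detected in few libraries were compared with those of control replicate 1. Of 108 to 118 genes per library 40 to 52 had a ratio near 1, with 27 to 33 within 5%, too few to settle relative depth, which is also unknown. Fold changes were computed as differences of log2(TPM + 1), with a pseudocount of 1, which understates changes of genes near or under 1 TPM. Genes at 1 TPM or more in at least 3 libraries were kept, which left 11355. The groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Values are given as mean ± SD of 3 libraries. Single sums of genes were compared with exact two-sided permutation tests in scipy 1.17.1, which cannot go below p = 0.1 with 3 against 3. Figures were drawn with matplotlib 3.10.9.

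The gene lists, 33 of pathways and 6 of markers of other cell types, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists held 748 genes, of which 712 were measured and 532 tested. Lists with at least 3 tested genes were compared with all other genes by limma's camera, with a preset correlation of 0.01 and adjustment over the 31 testable pathway lists. Camera with an estimated correlation and fry, which tests whether members move one way without comparing them with other genes, served as alternatives. Members were also counted with adjustment over the list alone. Annotation terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test against all tested genes that carry a term.

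The genes named were ANGPTL4, the galectin-7 genes and 11 Hedgehog genes whatever they showed (1 of these is not reported here), up to 12 called genes per direction with non-overlapping groups and a mean of at least 1 TPM, in each list the called members with the largest changes or otherwise the member with the smallest p, and any list member shown with its values. Other genes were chosen after their values were seen, and the text says so. Gene IDs were matched to the RefSeq annotation of GRCh38.p14 for coordinates, which are those of whole genes, and 17168 of 17225 matched. The values are per gene and do not separate exons or isoforms.

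The scripts were tested on simulated data made from these libraries, with 50 genes changed at each of 4 fold sizes. In simulated lists shifted by -0.08 on the log2 scale, camera found 20 of 20 draws and called 1 of 520 unchanged lists. The noise was drawn separately for each gene, so these counts say nothing about lists whose genes vary together. Alternatives were the replicate number as a block, leaving out each library in turn, no filter and a filter at 5 TPM, median-of-ratios scaling and quantile normalization of the deposited values, a pseudocount of 0.1, and limma without the trend. Alternatives chosen after seeing the data were the 5 distinct FPKM columns, the FPKM columns with the repeated one entered again, removal of trends on transcript length and GC content, camera over the annotation terms, camera with each estimated correlation held fixed, and principal components, correlations and counts of list members against the median of all genes, with ANGPTL4 left out of the principal components and correlations. Transcript length and GC content came from the reference transcripts and were found for 99.4% of the tested genes and for all tested list members.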

Results

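Messenger RNA was measured in AGS cells, an established human line derived from a gastric adenocarcinoma, in 2 groups of 3 libraries each. The control group was labelled as control or vector cells, and the other group overexpressed ANGPTL4 (angiopoietin-like 4), a secreted glycoprotein best known as an inhibitor of lipoprotein lipase. The series title ties ANGPTL4 to the Hedgehog pathway, to galectin-7, to metastasis and to angiogenesis, so the single comparison of the design asks what the cells' transcriptome looks like when ANGPTL4 is raised, and whether the genes of those processes move with it. The deposited table gave 17225 genes in TPM, the share of each gene among all transcripts, and 11355 of them reached 1 TPM in at least 3 libraries and were tested. Between 11311 and 11345 genes reached 1 TPM in each library. Read totals were not given, so the absolute depth is unknown. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

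ANGPTL4 (gene ID 51129; chromosome 19, 8364155 to 8374370 in GRCh38.p14) went from almost undetected to one of the more abundant transcripts of the cells. Its level was 0.25 ± 0.10 TPM in control libraries (SD, n = 3; 0.34, 0.14 and 0.27) and 1040 ± 31.3 TPM with overexpression (SD, n = 3; 1013, 1033 and 1075). The ratio of the means was 4161, and single pairs of libraries gave ratios from 2981 to 7676 because the control values lay near the lower end of the measured range. In rank, ANGPTL4 moved from place 12458 to place 131, and it made up 0.104% of all TPM. Its log2 fold change was 9.71 (SE 0.058) on the log2(TPM + 1) scale, which understates changes of genes with low values, with a limma adjusted p of 7.0e-13. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The table counts per gene, so transcripts from the introduced sequence and from the cells' own gene cannot be told apart. ANGPTL4 was the only tested member of its family, as the 7 others stayed under 1 TPM in too many libraries.

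**Figure D1:**
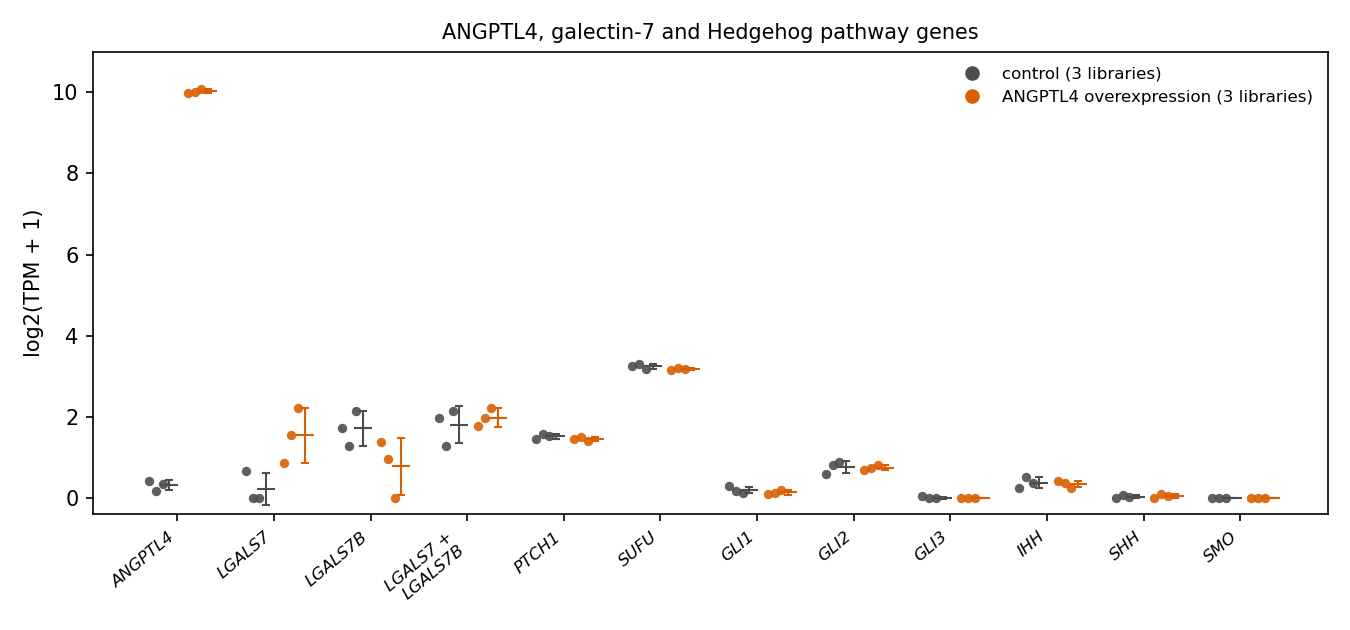
Levels of ANGPTL4, the galectin-7 genes and Hedgehog pathway genes on a log2(TPM + 1) axis, with a point per library and the mean ± SD of 3 libraries beside them, in grey for control and orange for ANGPTL4 overexpression. ANGPTL4 lies near 10 with overexpression and under 1 in control, whereas the sum of LGALS7 and LGALS7B and each Hedgehog gene overlap between the groups.

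Beyond ANGPTL4 the transcriptomes were nearly alike. No other gene passed the test: limma called 1 gene higher and 0 lower, with 750 genes at an unadjusted p under 0.05 where 568 would be expected by chance. Of these, 203 were higher and 547 lower, a split that became 354 higher and 324 lower with median-of-ratios scaling. With the TPM of all 6 libraries, limma also called ANGPTL4 alone with the replicate block, with other filters, scalings and pseudocounts, and without the variance trend. The 95% confidence interval of the fold change of TPM + 1 excluded a 1.5-fold difference in either direction for 11173 genes (98.4%), and a 1.25-fold difference for 9947 genes (87.6%). In genes with few TPM a larger change of TPM itself can lie within these bounds. Among 9704 genes with a mean of at least 5 TPM, 9676 were held within 1.5-fold of TPM + 1. On simulated data made from these libraries, the same test recovered 34 of 50 genes changed by 1.25-fold, 47 of 50 changed by 1.5-fold, and 50 of 50 changed by 2-fold, with 11 false calls among 11355 genes. There all changed genes had a mean of at least 5 TPM and were changed together, which eases the adjusted threshold for each. A gene changed alone faces a stricter threshold, so these shares do not give its chance of being called. The groups did not overlap in 1409 genes (12.4%), against the 10% that chance gives for 3 against 3. With ANGPTL4 left out, the first 2 principal components held 24.4% and 21.9% of the variance. Each set a single library apart, control replicate 1 (-11.8 on the first) and ANGPTL4 overexpression replicate 1 (-10.9 on the second), and not the groups. Correlations across genes without ANGPTL4 ran from 0.9965 to 0.9973 within groups and from 0.9964 to 0.9974 between them.

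The genes with the smallest p-values after ANGPTL4, named here after their values were seen, missed the adjusted threshold of the limma test. MTRNR2L2, a nuclear copy of the mitochondrial 16S ribosomal RNA sequence, had 5330 ± 108 TPM in control and 6320 ± 237 TPM with overexpression (SD, n = 3; log2 fold change 0.25, SE 0.03, adjusted p = 0.179). FOSB, a subunit of the AP-1 transcription factor, had 62.4 ± 0.56 and 53.5 ± 1.59 TPM (log2 fold change -0.22, SE 0.03, adjusted p = 0.383). CHCHD1, a protein of the mitochondrial ribosome, had 100.2 ± 2.76 and 86.5 ± 2.46 TPM, and the cytokine IL32 had 56.7 ± 1.64 and 65.4 ± 1.56 TPM. MTRNR2L2 passed the threshold without ANGPTL4 overexpression replicate 3 (adjusted p = 0.046, limma). It also passed in settings chosen after seeing the data, with the GC trend removed from all 6 libraries (0.032) and with the 5 distinct FPKM columns (0.035). Those FPKM columns lack the same replicate 3, so they are not a separate check. SVIP, an inhibitor of endoplasmic reticulum-associated degradation, had 56.3 ± 6.83 TPM in control and 41.3 ± 1.6 TPM with overexpression, and passed without control replicate 2 (adjusted p = 0.015, limma).

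**Figure D2:**
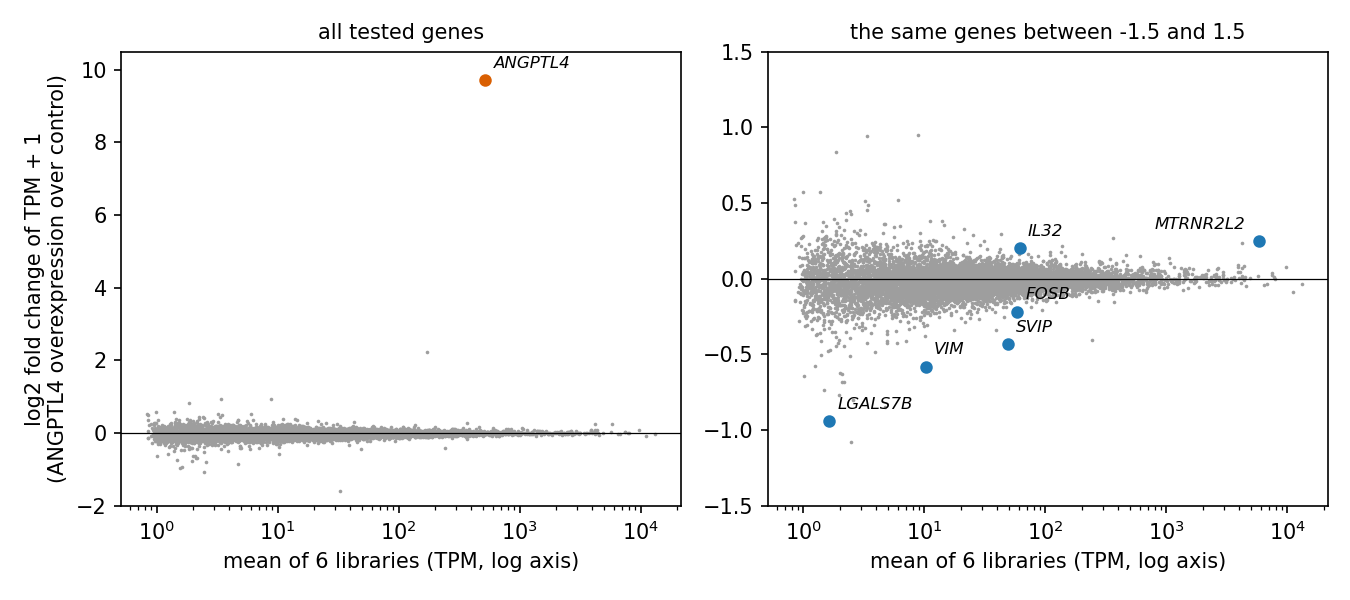
Log2 fold change of TPM + 1 (ANGPTL4 overexpression over control) against the mean of the 6 libraries in TPM on a log axis, a point per tested gene, over the whole range on the left and between -1.5 and 1.5 on the right. ANGPTL4, at 9.71, is the only gene called by limma, and U2AF1 and SULT1A3 lie outside the right panel at 2.22 and -1.6 without being called.

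Galectin-7 is encoded by a pair of near-identical neighbouring genes, LGALS7 (chromosome 19, 38770968 to 38773517) and LGALS7B (38789200 to 38791754), so the split of reads between them is uncertain. Summed, they stood at 2.60 ± 1.04 TPM in control and 2.99 ± 0.62 TPM with ANGPTL4 (SD, n = 3; exact permutation p = 0.7, with 0.1 the smallest possible). Taken singly the copies pointed in opposite directions. LGALS7 read 0.60, 0 and 0 TPM in control and 0.82, 1.96 and 3.65 TPM with ANGPTL4, and was too low to be tested. LGALS7B read 2.34, 1.44 and 3.43 TPM against 1.59, 0.96 and 0 TPM (log2 fold change -0.94, SE 0.33, limma adjusted p = 0.71). Of the 7 tested galectins, 0 were called by limma over all genes and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05, and camera gave adjusted p = 0.689 for the list. LGALS1, the most abundant, had 881 ± 36.2 and 868 ± 29.2 TPM, and LGALS3, which binds carbohydrates at the cell surface, had 380 ± 5.50 and 361 ± 16.7 TPM.

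Most Hedgehog pathway genes were under 1 TPM in these cells, and none of those tested passed. Of 26 listed components (ligands, receptors, transducers and GLI factors) 8 were tested, and limma called 0 of them over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. PTCH1, the receptor that is itself a target of the pathway (chromosome 9, 95442980 to 95516971), had 1.89 ± 0.12 TPM in control and 1.75 ± 0.10 TPM with ANGPTL4 (SD, n = 3; log2 fold change -0.07, 95% interval -0.28 to 0.15). SUFU, the cytosolic inhibitor of GLI proteins, had 8.5 ± 0.37 and 8.11 ± 0.14 TPM (log2 fold change -0.06, 95% interval -0.19 to 0.07). GLI1, the usual readout of pathway activity, had 0.15 ± 0.07 and 0.11 ± 0.05 TPM, and GLI2 had 0.71 ± 0.18 and 0.68 ± 0.07 TPM. The ligands SHH, IHH and DHH, with GLI3 and HHIP, stayed under 0.5 TPM in every library, and SMO, the signal-transducing receptor, was listed at 0 in all 6. The table lists 998 genes at 0 in all libraries, and absence cannot be told from a failed estimate there. Of the pathway's transcriptional targets 9 of 19 measured genes were tested and 0 were called by limma over all genes or adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. SPP1, that gene, encodes the matrix protein osteopontin and stood at 13 ± 0.79 and 11.3 ± 0.50 TPM (log2 fold change -0.18, SE 0.06, limma adjusted p = 0.66). CCND1, cyclin D1, stood at 241 ± 4.53 and 245 ± 2.65 TPM. The set tests gave adjusted p = 0.69 for components and 0.70 for targets with limma's camera. Pathway genes under 1 TPM in too many libraries were not tested.

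Although no single member reached the threshold over all genes, 5 of the 31 lists that could be tested were shifted as groups against all other genes with limma's camera at its preset correlation. None of the 5 stayed past the threshold with an estimated correlation, where camera uses 4 degrees of freedom. All 5 did with that correlation held fixed, but this drops the allowance for its uncertainty. Both settings count a negative estimate as 0. The fixed setting therefore does not offset the loss. The shifts were small, a few percent per gene. The median log2 fold change of all tested genes was itself -0.016, so members are counted below against that median as well as against 0. By fry, which does not compare a list with other genes, 7 lists passed: these 5, the unfolded protein response (adjusted p = 0.027) and gastric and intestinal identity (adjusted p = 0.022), both lower.

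Immediate early genes, which respond to growth factor and stress signals within minutes, were lower as a group. Of 25 tested members 22 lay below 0 and 18 below the median of all genes, with a median log2 fold change of -0.06, and 10 had non-overlapping groups in that direction. Camera gave adjusted p = 4.9e-06, and adjusted p = 0.068 with an estimated correlation. Over all genes 0 were called by limma, and 5 were called lower when adjusted over the list alone (DUSP2, DUSP6, FOS, FOSB and NR4A1), with 9 lower at an unadjusted p under 0.05. FOS, the AP-1 subunit, had 288 ± 2.51 TPM in control and 260 ± 15.1 TPM with ANGPTL4 (SD, n = 3; log2 fold change -0.15, SE 0.04). The nuclear receptor NR4A1 had 81.1 ± 1.18 and 71.0 ± 3.12 TPM (-0.19, SE 0.04). DUSP6, a phosphatase that inactivates ERK, had 10.4 ± 0.68 and 8.78 ± 0.19 TPM (-0.22, SE 0.06). EGR1 had 207 ± 5.53 and 196 ± 1.39 TPM (-0.08, SE 0.03).

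Targets of the hypoxia-inducible factors (HIF) were also lower as a group. Of 25 tested members 22 lay below 0 and 20 below the median of all genes (median log2 fold change -0.07) and 11 had non-overlapping groups, all lower. Camera gave adjusted p = 3.4e-05, and adjusted p = 0.249 with an estimated correlation. Limma called 0 over all genes, and 6 lower when adjusted over the list alone, namely NDRG1, EGLN3, PDK1, PFKFB4, SLC2A1 and BNIP3L, with 9 lower at an unadjusted p under 0.05. PDK1, the kinase that inhibits pyruvate dehydrogenase, had 6.68 ± 0.59 TPM in control and 5.03 ± 0.34 TPM with ANGPTL4 (log2 fold change -0.35, SE 0.08). EGLN3, a prolyl hydroxylase that acts on HIF, had 144 ± 1.04 and 134 ± 0.89 TPM (-0.11, SE 0.02). The glucose transporter SLC2A1 had 152 ± 3.49 and 142 ± 1.91 TPM (-0.10, SE 0.03), and VEGFA, the principal angiogenic growth factor, had 33.1 ± 1.27 and 31.6 ± 2.34 TPM (-0.07, SE 0.06). The glycolysis list, which shares SLC2A1, HK2 and PGK1 among others with the HIF list, had 14 of 18 members below 0 (13 below the median of all genes) and camera adjusted p = 0.057, with 0 called by limma over all genes or over the list alone and 2 lower at an unadjusted p under 0.05. It passed camera, lower, without ANGPTL4 overexpression replicate 3 (adjusted p = 0.0058) and with quantile normalization (0.012).

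Interferon-stimulated genes were higher as a group. Of 31 tested members 26 lay above 0 and 26 above the median of all genes, with a median log2 fold change of 0.04, and camera gave adjusted p = 4.9e-06, or adjusted p = 0.068 with an estimated correlation. Limma called 0 members over all genes and 0 adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, and only 3 of the 31 had non-overlapping groups, so the shift lay in the shared direction of small differences. The antiviral genes IFIT2 and IFIT3 had 57.6 ± 0.66 against 61.2 ± 1.70 TPM and 55.3 ± 0.78 against 58.8 ± 2.24 TPM (SD, n = 3). OASL had 41.4 ± 4.0 and 46.0 ± 2.91 TPM. Among HLA genes the list as a whole was not past camera (adjusted p = 0.249; its median and mean were below 0 and its test pointed up). HLA-B, a class I antigen-presenting molecule, was called higher when adjusted over the list alone, at 369 ± 0.61 and 396 ± 3.05 TPM (log2 fold change 0.10, SE 0.02).

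Targets of p53 and genes of matrix proteolysis made up the other shifted lists, both lower. Of 24 p53 targets 22 lay below 0 and 17 below the median of all genes (median log2 fold change -0.04; camera adjusted p = 0.012, and adjusted p = 0.269 with an estimated correlation). Limma called 0 of them over all genes, with 2 lower at an unadjusted p under 0.05. BTG2, an antiproliferative gene, was called lower when adjusted over the list alone and had 81.5 ± 1.80 and 73.7 ± 2.18 TPM (-0.14, SE 0.03). The kinase PLK3 had 12.2 ± 0.77 and 10.2 ± 0.55 TPM. Without control replicate 1 the p53 list had adjusted p = 0.075, and without ANGPTL4 overexpression replicate 3 it had 0.062. Of 17 matrix proteolysis genes 15 lay below 0 and 14 below the median of all genes (median -0.06; camera adjusted p = 0.042, and adjusted p = 0.269 with an estimated correlation), with 0 called by limma over all genes or adjusted over the list alone and 0 at an unadjusted p under 0.05. MMP14, a membrane-bound collagenase, had 172 ± 2.45 and 163 ± 7.12 TPM, and PLAT, tissue plasminogen activator, had 2.08 ± 0.05 and 1.68 ± 0.10 TPM. This call did not hold without control replicate 1 (0.228), without ANGPTL4 overexpression replicate 1 (0.122) or replicate 2 (0.166), with the 5 TPM filter (0.178), with median-of-ratios scaling (0.0501) or with the replicate block (0.0757).

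**Figure D3:**
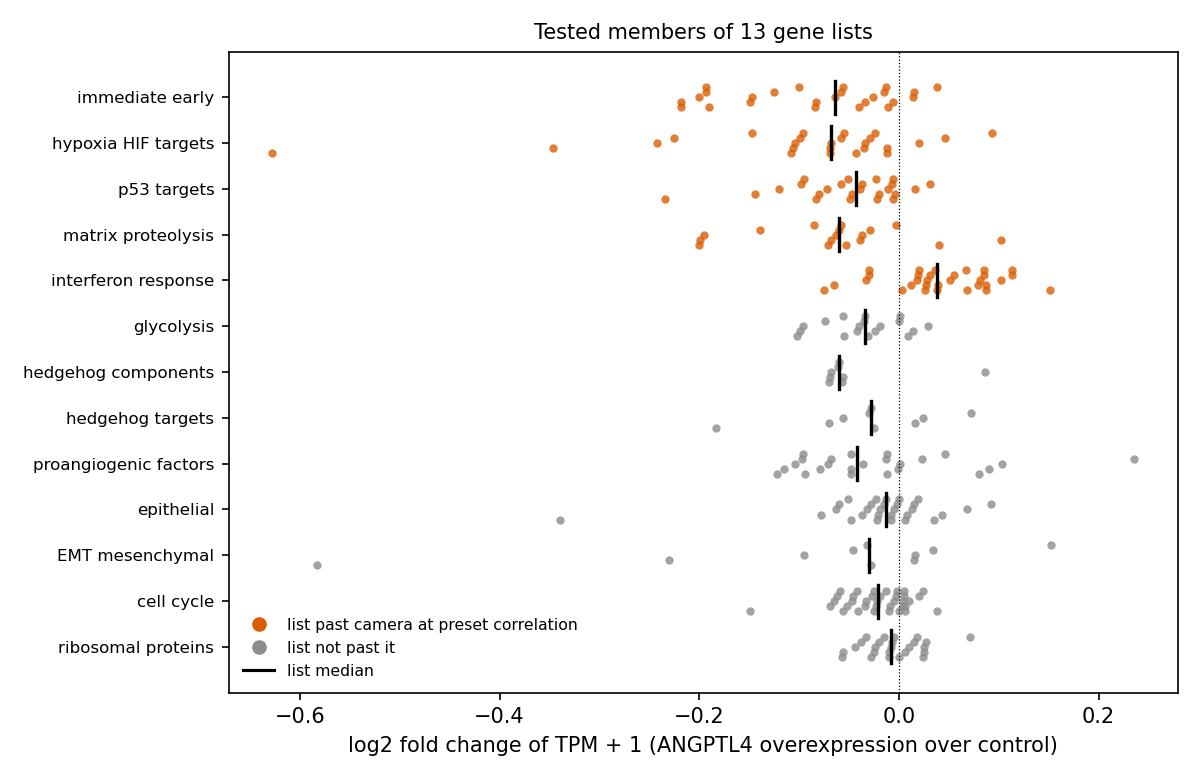
Log2 fold change of TPM + 1 for each tested member of 13 gene lists, with a black bar at each list's median. The 5 lists past limma's camera at the preset correlation are in orange and have medians from -0.07 to 0.04, and the 8 others are in grey.

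**Figure D4:**
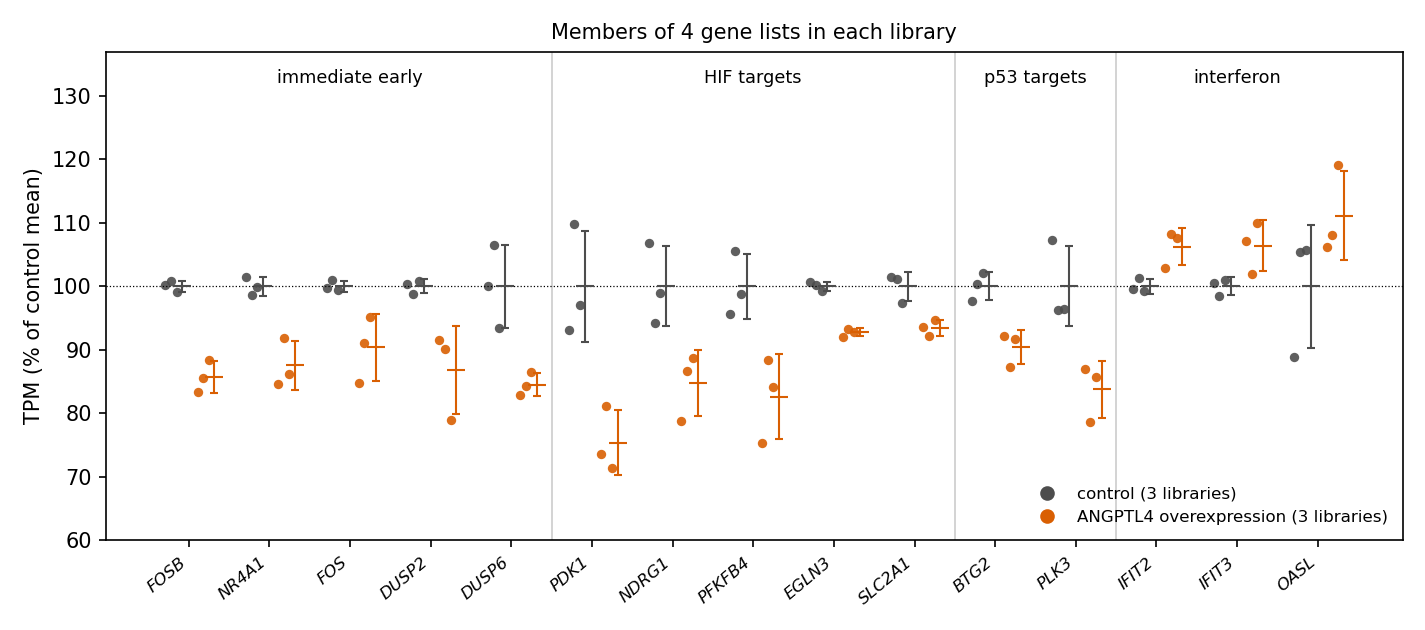
TPM of members of 4 lists in each library, as a percentage of the control mean, with points for libraries, bars for mean ± SD (n = 3), grey for control and orange for ANGPTL4 overexpression; the vertical axis does not start at 0. FOSB, NR4A1, PDK1 and BTG2 lie lower in each library with overexpression than in any control library, and IFIT2, IFIT3 and OASL lie higher, none of them called over all genes. The members shown do not stand for their lists. The immediate early and HIF genes shown are ones called when adjusted over the list alone. Of the 31 tested interferon members only 3 had non-overlapping groups.

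Apart from matrix proteolysis (above; camera adjusted p = 0.042, lower), none of 5 gene lists tied to angiogenesis and metastasis passed camera. Of their 90 tested genes limma called 0 over all genes, with 3 higher and 7 lower at an unadjusted p under 0.05. Of 24 proangiogenic factors 17 lay below 0 and 13 below the median of all genes (camera adjusted p = 0.749); adjusted over the list alone limma called CCN2 lower and EFNA1 higher. CCN2, a matricellular protein also counted among YAP and TGF-beta targets, had 237 ± 4.37 TPM in control and 218 ± 1.66 TPM with ANGPTL4 (SD, n = 3; log2 fold change -0.12, SE 0.03). The ligand EFNA1 had 98.5 ± 0.55 and 105.9 ± 0.81 TPM (0.10, SE 0.03). The chemokine CXCL8 had 2.38 ± 0.19 and 2.98 ± 0.36 TPM (0.24, SE 0.10). The 8 tested antiangiogenic factors gave adjusted p = 0.936, the 29 epithelial genes 0.749 and the 21 integrins and laminins 0.998. The 10 tested mesenchymal genes gave 0.960, with median and mean below 0 and a test pointing up. The epithelial keratin KRT19 had 1410 ± 31.8 and 1336 ± 28.4 TPM (-0.08, SE 0.03), and CDH1, E-cadherin, had 6.80 ± 0.06 and 7.02 ± 0.71 TPM.

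The remaining 16 lists did not pass camera either, and limma called 0 of their 285 tested genes over all genes, with 5 higher and 17 lower at an unadjusted p under 0.05. Among signalling targets, adjusted p was 0.689 for WNT, 0.209 for NOTCH, 0.689 for TGF-beta, 0.308 for YAP and 0.155 for NF-kappaB. Adjusted over the list alone, limma called HES4, a transcriptional repressor downstream of NOTCH (49.8 ± 2.95 against 41.7 ± 2.65 TPM; log2 fold change -0.25, SE 0.06), and LTBP3, which binds latent TGF-beta (24.5 ± 0.25 against 22.1 ± 0.67 TPM; -0.14, SE 0.04), both lower, and CCN2 in the TGF-beta and YAP lists. Among metabolic and stress lists, adjusted p was 0.929 for PPAR targets, 0.224 for cholesterol synthesis, 0.697 for fatty acid synthesis, 0.249 for the unfolded protein response, 0.618 for NRF2 targets, 0.697 for metallothioneins and 0.903 for heat shock genes. The cell cycle list gave 0.216, gastric and intestinal identity genes 0.209, replication-dependent histones 0.749 and ribosomal proteins 0.823. With quantile normalization 2 of these lists passed camera, both lower: the unfolded protein response (adjusted p = 0.029) and ribosomal proteins (adjusted p = 0.016). For the NRF2, metallothionein, heat shock, histone and ribosomal lists the median, the mean and the test did not share one sign. Genes encoded by the mitochondrial genome were not among the measured genes. Over 2768 combinations of annotation term and direction, Fisher's exact test had only 1 called gene to work with, ANGPTL4, so none could have passed and the test says nothing about the terms.

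Summed markers of other cell types did not separate the groups. Summed TPM of fibroblast markers was 11.3 ± 0.49 in control and 10.8 ± 0.61 with ANGPTL4 (SD, n = 3; exact permutation p = 0.4), of leukocyte markers 360 ± 12.4 and 358 ± 9.79 (exact p = 0.5), and of endothelial markers 0.29 ± 0.19 and 0.16 ± 0.07 (exact p = 0.4). Neuronal markers, nearly all of them TUBB3, gave 295 ± 9.38 and 290 ± 1.98 (exact p = 0.4), hepatocyte markers 12.2 ± 0.39 and 12.4 ± 1.21 (exact p = 0.8), and keratinocyte markers 37.4 ± 3.88 and 35.7 ± 2.43 (exact p = 0.6). The smallest p these 6 tests could give was 0.1. Sums follow their most abundant members. The 3 tested leukocyte markers had log2 fold changes from -0.21 to 0.00017, with a median of -0.12 and 0 called by limma.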

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

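ANGPTL4 kept its direction and its side of the threshold in all 17 other settings run, with a log2 fold change from 8.99 to 11.58, the low end on the FPKM scale and the high end with a pseudocount of 0.1. The FPKM settings, the length and GC settings and the annotation terms were chosen after seeing the data. The number of genes called higher ranged from 1 to 2 and the number lower from 0 to 1 when each library was left out in turn. Leaving out ANGPTL4 overexpression replicate 3 added MTRNR2L2 (2 genes higher), and leaving out control replicate 2 added SVIP (1 gene lower). MTRNR2L2 also passed with the 5 distinct FPKM libraries, which likewise lack ANGPTL4 overexpression replicate 3 (2 higher, limma adjusted p = 0.035). With the GC trend removed it passed on all 6 libraries (2 higher, adjusted p = 0.032). Entering the repeated FPKM column as a library gave 2 higher and 1 lower (FOSB, adjusted p = 0.033), and 1533 genes at an unadjusted p under 0.05 against 673 with the 5 distinct columns, because a copied library has no spread of its own. Median-of-ratios scaling turned the split of genes at an unadjusted p under 0.05 from 203 higher and 547 lower to 354 higher and 324 lower, so the surplus of lower genes depends on the scaling.

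The replicate numbers paired the libraries weakly at most. Same-numbered libraries correlated at 0.035 to 0.103 in their deviations from the group means, and the highest correlation of differently numbered ones was 0.011. All 6 correlated best with their own number. Deviations within a group sum to 0, so these 6 matches depend on one another. They are a weak hint of pairing from the data and not from the design. With the replicate block limma called 1 gene, as without it, and the matrix proteolysis list had adjusted p = 0.0757. That list also lost its call with the 5 TPM filter (0.178), median-of-ratios scaling (0.0501), the GC trend removed (0.0772) and an estimated correlation (0.269), and ranged from 0.0215 to 0.228 with a library left out. The p53 list lost its call with the 5 distinct FPKM libraries (0.0923) and an estimated correlation (0.269), and ranged from 0.0104 to 0.0754 with a library left out. The HIF, interferon and immediate early lists lost theirs only with an estimated correlation (0.249, 0.0683 and 0.0683) among 18 alternatives. All 5 lists passed with the estimated correlation held fixed, a test chosen after seeing the data. It drops the 4 degrees of freedom by which camera allows for an uncertain estimate. Negative estimates count as 0 in both settings. The fixed test therefore does not offset the losses with an estimated correlation. Glycolysis gained a call, lower, with quantile normalization (0.0119) and the 5 distinct FPKM libraries (0.0143), and ranged from 0.0058 (without ANGPTL4 overexpression replicate 3) to 0.324 with a library left out. The unfolded protein response passed with quantile normalization (0.0288) and fry (0.0268), and gastric and intestinal identity with fry (0.0220), all lower. Ribosomal proteins turned from higher (0.823) to lower with quantile normalization (0.0161). The Hedgehog lists stayed short of the threshold in all 18, between 0.240 and 0.959 for components and between 0.343 and 0.934 for targets. The 68 other tested genes that are named or shown, or chosen by the fixed rule, gave 1143 alternative values. Of these 6 were past the threshold, all of MTRNR2L2, SVIP and FOSB as given above (MTRNR2L2 also with the repeated FPKM column, adjusted p = 0.0060), and 7 had the other sign (in CDH1, LGALS1, SULT1A3 and TUBB3). Count-based alternatives were not run, as the table holds no counts. Without read totals, the precision of genes under about 1 TPM is not known.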

Other observations

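The tests weighed in this part were chosen after the results were seen, apart from the counts over other splits of the libraries for gene lists and for unadjusted p-values.

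Some further gene groups came out when camera was run over 1384 annotation terms of the deposited table. At the preset correlation 4 terms passed, all higher with ANGPTL4, and 0 with an estimated correlation. They were receptor antagonist activity, which here is led by the MTRNR2L genes (12 genes, mean log2 fold change 0.12, limma camera adjusted p = 0.0030), the cytosolic large ribosomal subunit (57 genes, 0.02, adjusted p = 0.014), the cytosolic ribosome (83 genes, 0.02, adjusted p = 0.014) and the polysomal ribosome (34 genes, 0.02, adjusted p = 0.026). The MTRNR2L genes are copies of the same sequence and were counted separately, so the p of the first term is likely too small. The fixed list of 25 ribosomal proteins did not pass camera (adjusted p = 0.823), but it passed with quantile normalization (adjusted p = 0.016), lower, against the direction of these terms. Its test pointed up in 13 of 18 alternatives, so the direction of ribosomal genes is not settled. The ribosomal shifts amount to about 1 to 2% per gene.

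The small shifts of the immediate early, interferon and HIF target lists are the pattern most worth following beyond ANGPTL4. Removing each library's trend on transcript length left 3 of the 3 lists past camera, and removing the trend on GC content left 3. Leaving out control replicate 1, the only control not labelled as vector cells, also left 3. These 3 lists were picked after the results were seen, so their staying is no test of those causes. The p53 and matrix proteolysis lists both passed with the length trend removed. With the GC trend removed p53 passed and matrix proteolysis did not (camera adjusted p = 0.0772). Without control replicate 1 neither passed (0.0754 for p53 and 0.228 for matrix proteolysis). The real grouping brought 5 lists past the threshold and the highest of the other splits of the 6 libraries 0, so that only 1 of the 10 splits, the real one, gave as many; 10 splits are too few for a share under 0.05. A response to ANGPTL4 or to a secreted product of the cells remains open, and so does a difference in cell density, feeding or harvest between the groups, which may move immediate early and HIF genes together and which the design does not separate from ANGPTL4. With an estimated correlation the camera adjusted p-values were 0.068, 0.068 and 0.249, where the test has 4 degrees of freedom. The estimates were -0.031, -0.011 and 0.048 against the preset 0.01. Camera counts a negative estimate as 0 in this setting and also with each estimate held fixed. Held fixed, the estimate gets no allowance for its uncertainty. The camera adjusted p was then 1.1e-07, 1.1e-07 and 0.0042. The first 2 lists could only gain there, as 0 lies below the preset, so these values add no support. The estimates rest on 6 libraries, so their own precision is not known.

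MTRNR2L genes, nuclear copies of the mitochondrial 16S ribosomal RNA, together held 9678 ± 288 TPM in control and 11454 ± 500 TPM with ANGPTL4 (SD, n = 3; exact permutation p = 0.1, the smallest possible). The 4 copies above 100 TPM had like shifts, with log2 fold changes from 0.21 to 0.27 and at most 0.481 standard errors between any pair. These standard errors treat the copies as independent, which shared reads would break. Copies that change together would also give like shifts, so the likeness does not tell the sources apart. Among copies below 100 TPM, MTRNR2L6 had 0.33, MTRNR2L10 0.20 and MTRNR2L3 -0.09. Reads from mitochondrial ribosomal RNA, assigned to its nuclear copies, are a candidate source that these values do not decide. A general rise of like size in nuclear transcripts for mitochondrial proteins was not seen in the 104 nuclear genes of oxidative phosphorylation. Their median log2 fold change was 0.0071 against 0.25 for MTRNR2L2. The SE of that median, 0.0069, was taken across genes as if they were independent. It does not measure the spread between libraries, and single genes of the group can differ from the median. Against all tested genes, with a median of -0.016, this group pointed up (limma camera adjusted p = 0.221), but by far less than MTRNR2L2. Whether more mitochondrial ribosomal RNA was present in the cells or more of it passed the selection of messenger RNA stays open, as transcripts of the mitochondrial genome were not among the measured genes.

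Besides ANGPTL4, 3 tested genes differed by 2-fold or more between the group means on the log2 scale without being called, and for U2AF1 and SULT1A3 the difference came from single libraries. U2AF1 read 1.57 TPM in control replicate 1 and 141 to 258 TPM in the other 5 libraries, and SULT1A3 read 0 TPM in ANGPTL4 overexpression replicate 1 and 27.5 to 43.5 TPM elsewhere. Each has a near-identical copy in the table, U2AF1L5 and SULT1A4. The sum with the copy varied by a CV of 1.85% for U2AF1, from 406 to 426 TPM, and of 3.53% for SULT1A3, where the single genes varied by 55.6% and 52.3%. Reads shared between the copies are a candidate explanation for both, and the LGALS7 pair, whose sum varied by 28.4% at 1.44 to 3.65 TPM against 120% for LGALS7 alone, may be split in the same way. The third gene was FAM131B, with 3.62 ± 2.47 and 1.30 ± 1.49 TPM.

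The count of called genes was 1 in the real grouping and at most 1 in the other splits, with 3 of 10 splits giving as many. At an unadjusted p under 0.05 the real grouping had 750 genes and the highest of the others 930, with 2 of 10 splits having as many. With 10 splits no share can go under 0.05.

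Control replicate 1, the library labelled as a control cell and not as a vector cell, had 21.0 TPM of VIM (vimentin, a mesenchymal intermediate filament), 2.75 times the median of the other 5 libraries, which ranged from 6.76 to 10.1 TPM. Of 10 other tested mesenchymal and fibroblast genes 0 were raised by 1.5-fold or more in it. It had 15 genes lying more than 0.5 outside the range of the others on the log2 scale, where the 5 other libraries had 6 to 13.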
